A study of Mus musculus with 6 samples.

How the data were processed

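Total RNA of skin biopsies from 6 samples was hybridised to an Affymetrix mouse gene array, with 2 samples each of intact skin, day 1 wounds and day 4 wounds. The labels give RNA integrity numbers between 7.7 and 9.1. The deposited values are log2 intensities per probe set, made with RMA per the submitters' processing notes, a method that corrects background, brings the arrays to a common distribution and summarises the probes. The RMA version is not given in the sources used here, and the deposited values are rounded to 2 decimals. They covered 35556 probe sets, and lower quartiles of 5.29 to 5.37, medians of 6.89 to 6.93 and upper quartiles of 8.47 to 8.54 on the 6 arrays were close to each other. Of the replicate pairs, 2.61% of probe sets in day 1 wounds, 2.38% in day 4 wounds and 3.02% in intact skin had identical values.

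Probe sets were joined to genes by the array annotation. Of them 21789 carried exactly 1 symbol, 1621 carried several and were left out, and 12146 were not in the annotation and were tested only apart from the genes. For 999 genes with more than 1 probe set the one with the highest mean over all 6 arrays was used, which gave 19938 genes. Symbols were checked against a RefSeq table of mouse assembly GRCm38.p6, used for names alone, in which 21698 gene identifiers were found and 91 were not, and 0 symbols had to be changed. Among genes with several probe sets that passed, another probe set also passed in the opposite direction for 6 of 296 genes on day 1, 3 of 272 on day 4 and 0 of 18 between the days, and opposite signs that did not pass were not counted.

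Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit with a mean per group, then eBayes with the default prior) on the deposited values of all 6 arrays, with 3 residual and 3.4 prior degrees of freedom. The 3 contrasts were day 1 wounds against intact skin, day 4 wounds against intact skin and day 4 against day 1 wounds. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes of a contrast, with a threshold of 0.05, and a moderated F test compared the 3 groups. Time classes are intersections of these calls: an early peak is higher on day 1 than intact and lower on day 4 than on day 1, a late rise is higher on day 4 than intact and than on day 1, and early trough and late fall have the signs turned. The number of arrays limits the precision of every value.

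The 30 gene lists were inflammatory chemokines, inflammatory cytokines and NF-kB targets, interferon-stimulated genes, immediate early and heat shock genes, hypoxia and glycolysis, cell cycle, structural extracellular matrix, matrix proteases and their inhibitors, growth factors of wound repair, cholesterol synthesis, circadian clock, oxidative phosphorylation, wound-edge keratinocyte genes, differentiated epidermis and cornified envelope, hair shaft and inner root sheath, sebaceous gland, and markers of basal keratinocytes, adipocytes, skeletal muscle, smooth muscle with pericytes and myofibroblasts, fibroblasts, endothelium, neutrophils, monocytes and macrophages, dendritic and Langerhans cells, T cells, B cells and plasma cells, mast cells, melanocytes and Schwann cells. They held 512 members, of which 473 were matched (3 by an older name) and 39 were not, and 3 genes stood in more than 1 list. Whole skin holds all of these cell types, so list values describe the biopsy and not a cell type. Lists were tested with camera at a preset inter-gene correlation of 0.01, again with the correlation estimated for each list, and with fry, which asks whether a list's genes move on balance in a direction and does not compare the list with other genes. With the correlation estimated, camera takes its p-values from the 3 residual degrees of freedom, which leaves little power. On day 1 the immediate early list had an estimated correlation of −0.0339, below the preset one. Its camera adjusted p still went from 0.00796 to 0.266. A lack of calls in that setting therefore does not tell whether correlation between genes accounts for a list's call. Apart from this list and the Schwann cell list (−0.1442), every list had an estimate above the preset value. The estimate was 0.9488 for hair genes, 0.7592 for neutrophil markers and 0.4159 for inflammatory cytokines and NF-kB targets. For such lists the preset correlation may give camera p-values that are too small. The samples, comparisons, tests, lists, the rule for named genes and all alternatives but 2 were chosen before the data were examined. The rule took, for each contrast, the 10 largest rises and the 10 largest falls among genes that passed, leaving out provisional names, and up to 4 members of each list with the smallest p, and allowed members that went against their list to be named.

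The alternatives were quantile normalization, cyclic loess and median centring of the deposited values, a mean-variance trend or a robust estimate in the prior, only the arrays of the 2 groups compared, removal of the dimmest 30% or 50% of genes, the mean of all probe sets of a gene, every probe set on its own, the replicate number as a term, and each array left out in turn. When an array was left out, its partner was assumed to vary like the other groups. After the data were seen, 2 alternatives were added that left out both wound arrays numbered 1 or both numbered 2. The share of calls common to both days was set beside 100 simulations of unchanged groups that shared the intact arrays, with noise drawn independently for each gene. The procedure was tested on simulated data with 200 changed genes among 19938: of changes of 1 and 2 log2 units it recovered 77% and 100% for day 1, 78% and 98% for day 4, and 82% and 96% between the days, with 5, 4 and 6 false calls. A list shifted in simulated data was called by camera, and 0 of the other lists were. The noise of these simulated data was also drawn independently for each gene. Those 0 calls therefore do not test lists whose genes move together.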

Results

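Transcript levels were measured with an Affymetrix mouse gene array in full-thickness skin biopsies of male BALB/c mice, an inbred albino strain, aged 5 to 6 weeks. Each wounded animal carried 2 punch wounds of 4 mm on the back, made down to the fascia. Biopsies of 8 mm took the wound together with the skin around it on day 1 or day 4, and intact skin was taken as the control, so that the wound itself made up 25% of the biopsy area. Each of the 3 groups held 2 arrays, whose number limits the precision of every estimate. The labels call the replicates biological but do not say whether an array held 1 animal or a pool, or 1 wound or both of a mouse. So n counts arrays, and the SDs give the spread between the 2 samples of a group. The limma p-values rest on a spread per gene estimated over all 3 groups together with the prior. Median log2 intensities lay between 6.89 and 6.93 on the 6 arrays. Over the 19938 genes measured, replicates correlated with r = 0.9967 in intact skin, 0.9891 in day 1 wounds and 0.9861 in day 4 wounds, where genes are not independent replicates. Wound arrays of the 2 days that share a replicate number correlated at 0.9895 (number 1) and 0.9905 (number 2). The first principal component held 79.8% of the variance and placed both intact arrays (59.41 and 54.98) apart from the wounds, which lay between −6.14 and −47.52. Among the 3 groups 6113 genes differed by the moderated F test, and this count was 4041 without day 1 wound replicate 2, 2396 without intact skin replicate 1 and 2654 without intact skin replicate 2.

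The comparison of day 1 wounds with intact skin asks which transcripts had changed early after the injury. Clec4e, a lectin receptor of myeloid cells, had a log2 intensity of 10.95 ± 0.16 (SD, n = 2) in day 1 wounds and 4.08 ± 0.04 (SD, n = 2) in intact skin, a 117-fold rise (log2 change 6.87, SE 0.12, adjusted p = 1.08e-05). The neutrophil-attracting chemokine Cxcl2 rose 104-fold, from 5.03 ± 0.25 to 11.74 ± 0.26 (SD, n = 2 each), and Ccl3, another chemokine of the innate response, rose 82.7-fold. Mmp8, the neutrophil collagenase, rose 67.6-fold, from 4.53 ± 0.11 to 10.61 ± 0.19 (SD, n = 2 each), and Retnlg, a resistin-like secreted protein of myeloid cells, rose 66.7-fold. The interleukin gene Il1b rose 44.5-fold, from 6.20 ± 0.24 to 11.68 ± 0.13 (SD, n = 2 each). The largest 10 rises also held Acod1 (49.4-fold), whose enzyme makes itaconate, the Schlafen gene Slfn4 (45.6-fold), the lectin receptor Clec4d (39.9-fold) and Prg4 (38.1-fold), which encodes the lubricant protein lubricin. All 10 kept their calls when any 1 of the arrays was left out, with a highest adjusted p of 0.00337. In intact skin Clec4e, Cxcl2, Mmp8 and Clec4d lay under the arrays' lower quartile of 5.29 to 5.37, where signal was not tested against background, so their folds and their order among the rises are approximate. The same limit holds for Cxcl3, Mmp13 and Cdh19, which lay under that quartile on at least 1 intact array.

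Of the immune lists, all but that of B cells and plasma cells were called up by camera on day 1, with medians above intact skin on both wound arrays. All 14 neutrophil markers rose (14 adjusted over the list alone), S100a9 by 27.2-fold, with a median log2 change of 4.65 (camera adjusted p = 1.58e-16, and adjusted p = 0.266 with an estimated correlation). All 15 inflammatory chemokines rose (15 adjusted over the list alone), among them Cxcl3 (30-fold) and the monocyte attractant Ccl12 (5.19-fold). Their median was 3.05 (adjusted p = 1.10e-14, and adjusted p = 0.219 with an estimated correlation). Of 22 inflammatory cytokines and NF-kB targets 20 rose and none fell (21 rose adjusted over the list alone), including the acute phase gene Saa3 (34.2-fold), the cytokine Osm (10.9-fold) and the NF-kB inhibitor Tnfaip3 (3.73-fold). The median was 1.99 (adjusted p = 1.91e-17, and adjusted p = 0.266 with an estimated correlation). All 15 interferon-stimulated genes rose (15 adjusted over the list alone), Rsad2 by 29.1-fold, Ifit1 by 20.1-fold, Ifit3 by 15.7-fold and Ifit2 by 9.45-fold. Their median was 2.64 (adjusted p = 6.81e-16, and adjusted p = 0.266 with an estimated correlation). Of 19 monocyte and macrophage markers 18 rose (18 adjusted over the list alone), among them the lipopolysaccharide co-receptor Cd14 (26.6-fold), the Fc receptor Fcgr1 (10.2-fold), the growth factor receptor Csf1r (2.42-fold) and the complement gene C1qb (2.21-fold). Their median was 1.91 (adjusted p = 7.46e-12, and adjusted p = 0.266 with an estimated correlation), and Gpnmb, a glycoprotein of macrophages that melanocytes also express, fell by 0.76. Neutrophil markers moved with the cytokine, chemokine and protease groups in the same biopsies. Of 13 dendritic and Langerhans cell markers 10 rose (10 adjusted over the list alone), including the lectin Clec10a (2.67-fold), the class II genes H2-Ab1 (1.86-fold) and H2-Eb1 (1.74-fold) and the integrin Itgax (1.68-fold), while the transcription factor Zbtb46 fell by 0.30. The list median was 0.75 (adjusted p = 6.36e-05, and adjusted p = 0.337 with an estimated correlation). Of 10 mast cell markers 6 rose (7 adjusted over the list alone), the proteases Cpa3 by 2.44-fold, Mcpt4 by 2.33-fold and Tpsb2 by 1.39-fold, whereas the receptor Kit, also a melanocyte gene, fell by 1.05. The median was 0.53 (adjusted p = 0.00411, and adjusted p = 0.337 with an estimated correlation). Of 12 T cell markers 3 rose (3 adjusted over the list alone), the receptor chains Cd3g (2.14-fold) and Cd3e (1.64-fold) and the adhesion molecule Cd2 (1.35-fold). The median was 0.15 (adjusted p = 0.0258, and adjusted p = 0.337 with an estimated correlation). The 9 B cell and plasma cell markers had a median of −0.19 (adjusted p = 0.394), and the adaptor Blnk fell by 0.65 as the single member past the threshold (1 adjusted over the list alone).

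Lists of tissue repair, hypoxia and activated epidermis genes were called up by camera on day 1, with medians above intact skin on both wound arrays. Of 19 matrix proteases and their inhibitors 13 rose (13 adjusted over the list alone), among them the collagenase Mmp13 (17.6-fold), the urokinase receptor Plaur (10.1-fold) and the aggrecanase Adamts4 (4.59-fold), and the inhibitor Timp3 fell by 0.59. The median was 1.28 (adjusted p = 3.00e-08, and adjusted p = 0.266 with an estimated correlation). Of 18 genes of hypoxia and glycolysis 15 rose and none fell (15 adjusted over the list alone), among them the lactate carrier Slc16a3 (5.45-fold), the glucose carrier Slc2a1 (3.58-fold), Bnip3 (2.63-fold) and the oxygen sensor Egln3 (2.2-fold). Their median was 1.02 (adjusted p = 9.52e-11, and adjusted p = 0.266 with an estimated correlation). Of 20 wound-edge keratinocyte genes 15 rose (15 adjusted over the list alone), with Krt16, a keratin of activated epidermis, 10.3-fold higher at 11.05 ± 0.03 against 7.68 ± 0.03 (SD, n = 2 each), the small proline-rich gene Sprr2d 7.04-fold and the cytokine Il1f9 6.3-fold higher. Their median was 1.11 (adjusted p = 9.45e-07, and adjusted p = 0.266 with an estimated correlation). Against the list, the gap junction genes Gjb2 and Gjb6 fell by 0.69 and 0.64 and the small proline-rich genes Sprr1a and Sprr2h fell by 0.51 and 0.74. Of 10 basal keratinocyte markers 6 rose (6 adjusted over the list alone), among them the hemidesmosome genes Itga6 (2.15-fold), Dst (1.61-fold), Itgb4 (1.4-fold) and Col17a1 (1.28-fold), while the cadherin Cdh3 fell by 0.53. Their median was 0.34 (adjusted p = 0.0362, and adjusted p = 0.358 with an estimated correlation). Of 19 growth factors of wound repair 14 rose (15 adjusted over the list alone), Hgf by 2.6-fold, Ccn1 by 2.03-fold, Inhba by 2.03-fold and Hbegf by 1.66-fold, whereas the receptor ligand Tgfa fell by 0.88. The median was 0.56 (adjusted p = 5.80e-06, and adjusted p = 0.337 with an estimated correlation). Of 21 genes of the structural extracellular matrix 11 rose and none fell (11 adjusted over the list alone), among them the proteoglycans Vcan (4.08-fold) and Lum (2.17-fold), Tnc (3.34-fold) and Thbs2 (2.11-fold). The median was 0.34 (adjusted p = 1.09e-05, and adjusted p = 0.358 with an estimated correlation). Of 16 immediate early and heat shock genes 6 rose (7 adjusted over the list alone), including the transcription factors Atf3 (3.42-fold) and Fos (3.33-fold) and the stress gene Ier3 (2.37-fold), while Egr3 and Egr2 fell by 0.86 and 0.58. The median was 0.21 (adjusted p = 0.00796, and adjusted p = 0.266 with an estimated correlation).

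Endothelial and skeletal muscle lists were called up by camera on day 1, with medians above intact skin on both wound arrays. Of 16 endothelial markers 11 rose and none fell (13 rose adjusted over the list alone), among them the growth factor receptors Flt1 (2.07-fold) and Kdr (1.91-fold) and the surface proteins Esam (1.99-fold) and Emcn (1.89-fold). Their median was 0.46 (adjusted p = 8.51e-07, and adjusted p = 0.337 with an estimated correlation). Of 22 skeletal muscle markers 19 rose and none fell (20 rose adjusted over the list alone), the fast myosin Myh4 by 2.54-fold, the calcium channel Ryr1 by 2.46-fold, the glycogen phosphorylase Pygm by 1.79-fold and the sarcomere gene Myoz1 by 1.61-fold. Their median was 0.83 (adjusted p = 7.69e-12, and adjusted p = 0.337 with an estimated correlation), so muscle transcripts rose in the same biopsies as those of hypoxia and glycolysis. Of 14 fibroblast markers 5 rose and 2 fell (7 and 2 adjusted over the list alone), with the growth factor receptor Pdgfra 3.34-fold higher and the peptidase Dpp4 lower by a log2 change of −1.32, at a median of 0.29 (adjusted p = 0.159). Of 12 smooth muscle, pericyte and myofibroblast markers 3 rose and 2 fell (3 and 2 adjusted over the list alone), at a median of 0.03 (adjusted p = 0.414), with the filament gene Des 2.22-fold and the receptor Pdgfrb 1.95-fold higher and the myosin light chain Myl9 at −0.47. Of 20 genes of differentiated epidermis and the cornified envelope 6 rose and 4 fell (8 and 5 adjusted over the list alone), at a median of 0.24 (adjusted p = 0.0811). Calm4 and the lipoxygenase Alox12b were higher by 0.85 and 1.20, and the transglutaminase Tgm3 and involucrin (Ivl) were at −1.49 and −1.34. The 12 sebaceous gland genes had a median of 0.06 and a mean of −0.03 with camera's direction up and fry's down (adjusted p = 0.795), and 1 rose and 2 fell (1 and 2 adjusted over the list alone), with the melanocortin receptor Mc5r at −1.37. Of 13 adipocyte markers 2 rose and 5 fell (2 and 5 adjusted over the list alone), the lipogenic gene Thrsp being 3.99-fold lower and the lipase Lipe at −0.47. The median was −0.12 (adjusted p = 0.23). Of 14 circadian clock genes 4 rose and 1 fell (4 and 1 adjusted over the list alone), at a median of 0.06 (adjusted p = 0.373), with Ciart and Per1 each at 0.76 and Bhlhe41 2-fold lower. Of 6 Schwann cell markers 2 rose (2 and 1 lower adjusted over the list alone), the cadherin Cdh19 by 1.8-fold and the myelin gene Mbp by 1.43-fold, at a median of 0.28 (adjusted p = 0.215). Among 21 genes of oxidative phosphorylation limma called 0 (0 adjusted over the list alone and 0 at an unadjusted p under 0.05). The median was 0.06 (adjusted p = 0.497).

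Transcripts known from the hair follicle led the falls on day 1. Krt28, a keratin of the inner root sheath, stood at 5.52 ± 0.94 in day 1 wounds and 11.81 ± 0.01 in intact skin (SD, n = 2 each), 78.2-fold lower (log2 change −6.29, SE 1.37, adjusted p = 0.0164). Krt28 and Krt26 lay under the lower quartile on 1 of the day 1 arrays, so their folds and their place among the falls are approximate. The root sheath keratins Krt26, Krt72 and Krt73 were 62-fold, 49.7-fold and 39-fold lower, and the hair cortex keratin Krt31 was 33.1-fold lower. Of the keratin-associated genes of the hair shaft, Krtap24-1 was 47-fold, Krtap14 38.1-fold and Krtap26-1 30.7-fold lower. The channel gene Calhm4 was 44.8-fold lower, and Gprc5d, an orphan receptor of hair-forming cells, was 40.1-fold lower. These 10 falls did not outlast the loss of an array: 6 lost their calls without day 1 wound replicate 1, 10 without day 1 wound replicate 2 and 10 without either of the intact skin arrays, with a highest adjusted p of 0.208. Over the list of 21 genes of the hair shaft and inner root sheath 12 fell and none rose (16 fell adjusted over the list alone). The list median was −4.14, 17.6-fold lower (adjusted p = 3.77e-06, and adjusted p = 0.454 with an estimated correlation), and it was −2.85 on day 1 wound replicate 1 and −6.03 on day 1 wound replicate 2. Krt35, a hair shaft keratin, was 17.4-fold lower and the homeobox gene Msx2 10.6-fold lower. Krt32, a keratin of the hair cuticle, was 7.39-fold lower. Foxn1, the transcription factor mutated in nude mice, was 6.39-fold lower at 7.71 ± 0.41 against 10.39 ± 0.04 (SD, n = 2 each). Krt32, Msx2 and Foxn1 kept their calls with any 1 array left out. All 8 melanocyte markers fell (8 adjusted over the list alone), Dct by 2.26, Tyrp1 by 2.20, Slc45a2 by 1.32 and the regulator Mitf by 1.24. Their median was −1.31 (adjusted p = 2.91e-04, and adjusted p = 0.358 with an estimated correlation). The melanocyte median lay at −1.34 and −1.40 on the day 1 arrays and at 0.50 and −0.50 on the intact arrays. Of 28 cell cycle genes 14 fell and none rose (16 fell and 2 rose adjusted over the list alone), in the same biopsies as the hair genes. The kinesin Kif11 fell by 0.65, the proliferation antigen Mki67 by 0.64, the checkpoint kinase Bub1b by 0.59 and cyclin Ccnb2 by 0.53. The median was −0.33 (adjusted p = 2.20e-04, and adjusted p = 0.337 with an estimated correlation), at −0.32 and −0.34 on the 2 day 1 arrays. Of 14 genes of cholesterol synthesis 3 fell and none rose (3 adjusted over the list alone), the feedback regulator Insig1 by 1.40, Nsdhl by 0.46 and mevalonate kinase (Mvk) by 0.45. The median was −0.16 (adjusted p = 0.0444, and adjusted p = 0.566 with an estimated correlation).

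In all, 2927 genes were higher and 2915 lower in day 1 wounds than in intact skin, of which 963 and 479 differed at least 2-fold. The share of higher genes, 50.1%, depended on scaling: cyclic loess gave 3383 higher and 2376 lower (58.7%), and median centring gave 2793 and 3294 (45.9%). Without day 1 wound replicate 2 the counts were 1871 and 1478, without intact skin replicate 1 they were 1773 and 1376, and without intact skin replicate 2 they were 1934 and 1459. Camera called 17 lists up and 4 down, and fry called 20. Of the lists that camera called, fry did not call hair genes (fry adjusted p = 0.081) or cholesterol synthesis (0.0687). It called Schwann cell markers (0.0215), which camera did not. With an estimated correlation camera called 0 (lowest adjusted p 0.219), but with 3 residual degrees of freedom that setting had little power in every comparison. The basal keratinocyte call ended without day 1 wound replicate 1 (adjusted p = 0.137) and without intact skin replicate 1 (0.0736). The cholesterol synthesis call ended without day 1 wound replicate 1 (0.304), intact skin replicate 1 (0.0592) or intact skin replicate 2 (0.0725), and the T cell call without day 1 wound replicate 1 (0.0881) or intact skin replicate 2 (0.132). The basal keratinocyte call also ended with cyclic loess (0.0961) and without the dimmest 30% of genes (0.0775), and without the dimmest 50% it (0.133), the mast cell call (0.362) and the immediate early call (0.0894) ended. Of 116 list members that passed and were chosen by the rule for named genes, 93 kept their calls without any 1 array, and 11, 16, 19 and 17 lost them without day 1 wound replicates 1 and 2 and intact skin replicates 1 and 2. Probes shared between close relatives leave single values of the keratin, keratin-associated, Schlafen, Sprr2, Stfa, Ifi200 and Saa families uncertain.

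**Figure D1:**
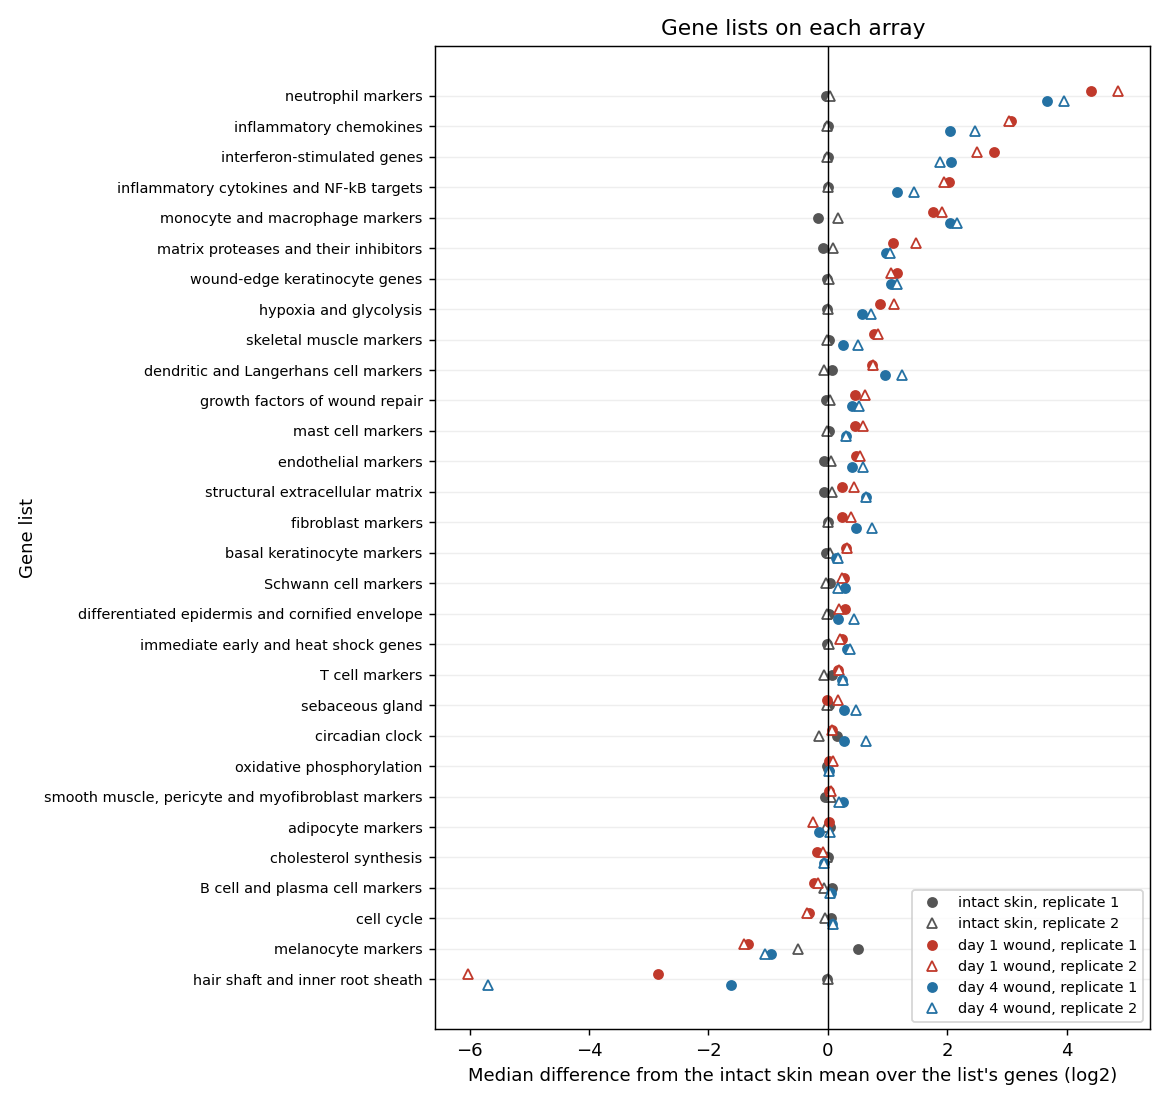
The median difference from the intact skin mean (log2, horizontal axis) over the genes of each of the 30 lists (vertical axis) is plotted for each of the 6 arrays, with day 1 wounds in red, day 4 wounds in blue, intact skin in grey, filled circles for replicate 1 and open triangles for replicate 2. Neutrophil markers lie highest, at 4.41 and 4.86 on the day 1 arrays, and hair genes lowest, at −2.85 and −6.03, with the replicates of each wound day far apart.

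The comparison of day 4 wounds with intact skin asks which transcripts differed from unwounded skin later in repair. Cxcl2 was 88-fold higher, at 11.49 ± 0.10 against 5.03 ± 0.25 (SD, n = 2 each), and Ccl3 was 73.3-fold higher. Clec4e was 60.3-fold higher (log2 change 5.92). The keratin Krt6b, induced in injured epidermis, rose 38.5-fold, from 7.38 ± 1.55 to 12.64 ± 0.01 (SD, n = 2 each, log2 change 5.27, SE 0.62). Il1b rose 36.1-fold to 11.38 ± 0.16 (SD, n = 2). The largest 10 rises further held the protease inhibitor Stfa3 (34.9-fold), Acod1 (33.9-fold), Slfn4 (32.3-fold), Clec4d (25.5-fold) and Trem1 (25.1-fold), an amplifying receptor of myeloid cells. All 10 kept their calls with any 1 array left out, with a highest adjusted p of 0.0181. The folds of Cxcl2, Clec4e, Clec4d, Mmp13, Jchain and Cdh19 are approximate, because they lay under the arrays' lower quartile on at least 1 intact array, as is that of Stox1, which did so on 1 of the day 4 arrays.

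Of the immune lists, all but those of mast cells and of B cells and plasma cells were called up by camera on day 4, with medians above intact skin on both wound arrays. All 14 neutrophil markers rose (14 adjusted over the list alone), S100a9 by 19.7-fold and S100a8 by 17-fold. Their median was 3.81 (adjusted p = 1.34e-14, and adjusted p = 0.281 with an estimated correlation). All 15 inflammatory chemokines rose (15 adjusted over the list alone), among them Ccl12 (2.74-fold) and Cxcl16 (2.69-fold). The median was 2.26 (adjusted p = 5.76e-13, and adjusted p = 0.259 with an estimated correlation). Of 22 inflammatory cytokines and NF-kB targets 16 rose and none fell (16 adjusted over the list alone), including Saa3 (20.3-fold), Osm (7.86-fold) and Tnf (4.89-fold). Their median was 1.29 (adjusted p = 3.34e-12, and adjusted p = 0.281 with an estimated correlation). Of 15 interferon-stimulated genes 14 rose (15 adjusted over the list alone), Rsad2 by 17.2-fold, Ifit1 by 12.6-fold, Ifit3 by 9.95-fold and Ifit2 by 6.25-fold. The median was 1.97 (adjusted p = 9.57e-14, and adjusted p = 0.281 with an estimated correlation). Of 19 monocyte and macrophage markers 18 rose (18 adjusted over the list alone), with Cd14 12.7-fold, Csf1r 3.4-fold, C1qc 3.25-fold and C1qb 2.96-fold higher and Gpnmb lower at −0.62. Their median was 2.13 (adjusted p = 3.12e-12, and adjusted p = 0.281 with an estimated correlation). Of 13 dendritic and Langerhans cell markers 11 rose (12 adjusted over the list alone), Clec10a by 3.53-fold, H2-Eb1 by 2.47-fold, H2-Ab1 by 2.35-fold and the cytokine receptor Flt3 by 2.04-fold, while Zbtb46 fell by 0.36. The median was 1.09 (adjusted p = 1.20e-06, and adjusted p = 0.287 with an estimated correlation). Of 12 T cell markers 3 rose (3 and 1 lower adjusted over the list alone), Cd3g by 1.88-fold, the co-receptor Cd4 by 1.82-fold and Cd2 by 1.66-fold. Their median was 0.23 (adjusted p = 0.00716, and adjusted p = 0.291 with an estimated correlation). Of 10 mast cell markers 4 rose and 1 fell (6 and 1 adjusted over the list alone), at a median of 0.34 (adjusted p = 0.0587), with Cpa3 2.05-fold, Mcpt4 1.99-fold and Cma1 1.39-fold higher and Kit at −0.96. Of 9 B cell and plasma cell markers 1 rose and 1 fell (1 and 1 adjusted over the list alone), the immunoglobulin joining chain Jchain 2.03-fold higher and Blnk at −0.78, at a median of 0.08 (adjusted p = 0.718).

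Matrix, fibroblast and vessel lists were called up by camera on day 4, with medians above intact skin on both wound arrays. Of 21 genes of the structural extracellular matrix 15 rose and none fell (18 adjusted over the list alone), among them Tnc (3.13-fold), Lum (3.07-fold), Thbs2 (2.68-fold) and the fibrillar collagen Col5a2 (2.01-fold). The median was 0.63 (adjusted p = 7.25e-09, and adjusted p = 0.322 with an estimated correlation). Of 14 fibroblast markers 8 rose (11 adjusted over the list alone), with Pdgfra 2.69-fold, the collagen Col14a1 1.93-fold, Dpt 1.64-fold and Cd34 1.32-fold higher, while Dpp4 fell by 0.43. Their median was 0.58 (adjusted p = 9.53e-05, and adjusted p = 0.281 with an estimated correlation). Of 19 matrix proteases and their inhibitors 16 rose (16 adjusted over the list alone), Mmp13 by 9.88-fold, the gelatinase Mmp9 by 6.7-fold and Plaur by 6.32-fold, and Timp3 fell by 0.71. The median was 0.97 (adjusted p = 8.60e-10, and adjusted p = 0.281 with an estimated correlation). Of 16 endothelial markers 10 rose and none fell (12 adjusted over the list alone), among them Esam (1.78-fold), Emcn (1.67-fold), Flt1 (1.52-fold) and the clotting factor Vwf (1.44-fold). Their median was 0.49 (adjusted p = 3.55e-06, and adjusted p = 0.376 with an estimated correlation). Of 12 smooth muscle, pericyte and myofibroblast markers 5 rose (5 adjusted over the list alone), Pdgfrb by 2.04-fold, Des by 1.78-fold and the pericyte regulator Rgs5 by 1.74-fold, and the proteoglycan Cspg4 fell by 0.51. The median was 0.22 (adjusted p = 0.0117, and adjusted p = 0.376 with an estimated correlation). Of 19 growth factors 9 rose (11 adjusted over the list alone), Hgf by 2.73-fold, Tgfb3 by 1.9-fold and Tgfb1 by 1.74-fold, and Tgfa fell by 0.86. The median was 0.47 (adjusted p = 8.13e-04, and adjusted p = 0.406 with an estimated correlation). Of 18 genes of hypoxia and glycolysis 13 rose and none fell (15 adjusted over the list alone), Slc16a3 by 4.45-fold, Slc2a1 by 3.23-fold, Bnip3 by 2.34-fold and Egln3 by 2.2-fold. Their median was 0.64 (adjusted p = 3.20e-08, and adjusted p = 0.291 with an estimated correlation). Of 22 skeletal muscle markers 12 rose and none fell (13 adjusted over the list alone), Ryr1 by 2.05-fold, the actinin Actn3 by 2.01-fold, Myh4 by 1.78-fold and nebulin (Neb) by 1.6-fold. The median was 0.37 (adjusted p = 2.06e-06, and adjusted p = 0.406 with an estimated correlation). Of 16 immediate early and heat shock genes 8 rose (9 adjusted over the list alone), including Atf3 (2.68-fold), Fos (2.21-fold) and Ier3 (1.8-fold), while Egr3, Egr2 and Egr1 fell by 0.92, 0.56 and 0.42. The median was 0.34 (adjusted p = 0.00716, and adjusted p = 0.281 with an estimated correlation).

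The wound-edge, differentiated epidermis and sebaceous lists were called up by camera on day 4 and the hair and melanocyte lists down, each with both wound arrays on that side of intact skin. Of 20 wound-edge keratinocyte genes 15 rose (15 adjusted over the list alone), with Krt16 13.8-fold higher at 11.47 ± 0.01 against 7.68 ± 0.03 (SD, n = 2 each), Sprr2d 9.13-fold, Il1f9 5.26-fold and Sprr1b 2.11-fold higher. Gjb2, Sprr1a and Sprr2h fell by 0.33, 0.56 and 0.94 against the list's median of 1.13 (adjusted p = 4.04e-07, and adjusted p = 0.281 with an estimated correlation). Of 20 genes of differentiated epidermis and the cornified envelope 8 rose (10 adjusted over the list alone), Calm4 by 1.44, the protease Casp14 by 1.38, the filaggrin relative Hrnr by 0.98 and the suprabasal keratin Krt1 by 0.84, whereas Ivl, Tgm3 and Tgm1 fell by 0.78, 0.63 and 0.43. The median was 0.28 (adjusted p = 0.0109, and adjusted p = 0.406 with an estimated correlation). Of 10 basal keratinocyte markers 5 rose and 1 fell (5 and 2 adjusted over the list alone), Itga6 1.95-fold and Krt14 1.52-fold higher and Cdh3 at −0.84. Their median was 0.16 (adjusted p = 0.132). Of 12 sebaceous gland genes 5 rose (8 adjusted over the list alone), the lipid synthesis genes Awat1 by 0.87, Elovl3 by 0.52 and Elovl4 by 0.47, and Mc5r fell by 1.12. The median was 0.38 (adjusted p = 0.0235, and adjusted p = 0.406 with an estimated correlation). Of 14 circadian clock genes 4 rose (6 adjusted over the list alone), Ciart by 0.82, Per1 by 0.80 and Clock by 0.55, and Bhlhe41 fell by 0.50. The median was 0.47 (adjusted p = 0.0109, and adjusted p = 0.376 with an estimated correlation). Of 28 cell cycle genes 4 rose and none fell (4 adjusted over the list alone), the replication genes Mcm6 by 0.56, Mcm4 by 0.49 and Pcna by 0.41 and the topoisomerase Top2a by 0.34. The median was 0.07 (adjusted p = 0.039, and adjusted p = 0.406 with an estimated correlation), and that call ended with quantile normalization (adjusted p = 0.153), cyclic loess (0.0788) and median centring (0.0727). Of 21 genes of the hair shaft and inner root sheath 6 fell and none rose (11 adjusted over the list alone), Msx2 being 7.89-fold, the hair keratin Krt34 7.78-fold, Foxn1 5.68-fold and Krt32 4.82-fold lower. The list median was −3.24, 9.45-fold lower (adjusted p = 1.19e-05, and adjusted p = 0.406 with an estimated correlation), and lay at −1.63 on day 4 wound replicate 1 and −5.70 on day 4 wound replicate 2. The largest 10 falls held Krtap5-5 at −4.38 (SE 1.07, adjusted p = 0.0268, 20.8-fold lower), Krtap24-1 (19.6-fold lower), Krt39 (17.4-fold lower), Krtap26-1 (17-fold lower), the receptor subunit Gabrp (11.8-fold lower), Stox1 (11.6-fold lower), the lipoxygenase Alox8 (11-fold lower), Krtap10-10 (11-fold lower), Psors1c2 (10.9-fold lower) and the hair keratin Krt82 (10.9-fold lower). Of these, Alox8 and Krt82 kept their calls with any 1 array left out, and 3 lost theirs without day 4 wound replicate 2, 8 without intact skin replicate 1 and 7 without intact skin replicate 2, with a highest adjusted p of 0.142. Of 8 melanocyte markers 5 fell and none rose (8 adjusted over the list alone), Tyrp1 by 1.80, Dct by 1.44, Mitf by 0.98 and the carrier Oca2 by 0.89. Their median was −0.96 (adjusted p = 0.00149, and adjusted p = 0.406 with an estimated correlation).

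The remaining lists were not called on day 4. Of 13 adipocyte markers 3 fell and none rose (3 adjusted over the list alone), with the hormone Lep at −0.91 and Lipe at −0.63, at a median of −0.03 (adjusted p = 0.281). Of 14 genes of cholesterol synthesis 2 rose and 2 fell (2 and 2 adjusted over the list alone), Cyp51 at 0.39, Msmo1 at 0.35, Insig1 at −1.09 and Mvk at −0.39, at a median of −0.07 (adjusted p = 0.878). Of 6 Schwann cell markers 2 rose (3 adjusted over the list alone), Cdh19 by 2.74-fold and Mbp by 1.25-fold, at a median of 0.26 (adjusted p = 0.133). Of 21 genes of oxidative phosphorylation 2 rose (2 adjusted over the list alone), the respiratory chain genes Ndufb5 at 0.42 (adjusted p = 0.0114) and Atp5c1 at 0.31 (adjusted p = 0.0241). The median was 0.03 (adjusted p = 0.354), and −0.02 with cyclic loess and −0.03 with median centring.

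In all, 2958 genes were higher and 2413 lower in day 4 wounds than in intact skin, 753 and 349 of them at least 2-fold. With each array centred on its median the split was 2574 higher to 3345 lower, a higher share of 43.5% against 55.1%. Without day 4 wound replicate 2 the counts were 1659 and 1269, without intact skin replicate 1 they were 1393 and 853, and without intact skin replicate 2 they were 1627 and 958. Camera called 21 lists up and 2 down, and 0 with an estimated correlation, where the lowest adjusted p was 0.259, and fry called 18. Of the lists that camera called, fry did not call hair (fry adjusted p = 0.108), melanocyte (0.0727) and skeletal muscle (0.0534). The same held for cell cycle (0.0677), circadian clock (0.0693), growth factors (0.0538) and sebaceous gland (0.102). Fry called basal keratinocyte (0.0197) and Schwann cell markers (0.0084), which camera did not. The cell cycle call ended without day 4 wound replicate 1 (adjusted p = 0.0665) or intact skin replicate 2 (0.178), the circadian and sebaceous calls without day 4 wound replicate 2 (0.0627 each), and the smooth muscle call without intact skin replicate 1 (0.0533). Without the dimmest 50% of genes the calls for cell cycle (0.22), differentiated epidermis (0.107), growth factors (0.0555), immediate early genes (0.1), sebaceous gland (0.148) and smooth muscle (0.107) ended. Without the dimmest 30% those for cell cycle (0.137), differentiated epidermis (0.0515), circadian clock (0.0515), sebaceous gland (0.0832) and smooth muscle (0.0501) ended. Cyclic loess ended those for differentiated epidermis (0.0674) and sebaceous gland (0.0844). Of 123 list members that passed and were chosen by the rule, 80 kept their calls without any 1 array. Calls were lost for 1, 1, 12, 23, 33 and 31 of them when day 1 wound replicates 1 and 2, day 4 wound replicates 1 and 2 and intact skin replicates 1 and 2 were left out in turn.

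The comparison of day 4 with day 1 wounds asks how the wound transcriptome moved on between these time points. Rptn, which encodes the cornified envelope protein repetin, rose 7.7-fold from 6.76 ± 0.45 on day 1 to 9.70 ± 0.14 on day 4 (SD, n = 2 each, log2 change 2.95, SE 0.20, adjusted p = 0.00816), with intact skin at 8.06 ± 0.12 (SD, n = 2). The Wnt modulator Sfrp2 rose 7.11-fold, from 7.67 ± 0.18 to 10.50 ± 0.18, and the embryonic myosin Myh3 rose 5.17-fold, from 5.28 ± 0.08 to 7.65 ± 0.42 (SD, n = 2 each). The secreted protein gene Cthrc1, expressed by activated fibroblasts, rose 3.01-fold from 8.06 ± 0.01 to 9.65 ± 0.04 (SD, n = 2 each, adjusted p = 0.00437). The cytokine Il6 fell 6.52-fold, from 8.18 ± 0.04 to 5.48 ± 0.74 (SD, n = 2 each, log2 change −2.71, SE 0.35, adjusted p = 0.0291), with intact skin at 4.14 ± 0.45 (SD, n = 2). Further rises were Lrrc17 (5.33-fold), cardiac actin Actc1 (4.74-fold), the protease Tmprss11b (4.56-fold), the steroid-metabolising genes Akr1d1 (3.72-fold) and Akr1c18 (3.32-fold), and Thrsp (2.78-fold). Further falls were Rrad (6.04-fold) and Ankrd1 (5.17-fold), which stressed muscle induces, the acute phase genes Ptx3 (6-fold) and Saa2 (4.99-fold), the neutrophil antigen Ly6g (5.76-fold), Mmp8 (4.63-fold), the interferon-inducible Ifi214 (4.52-fold), Retnlg (4.29-fold) and the small heat shock gene Hspb7 (3.73-fold). Clec4e was lower on day 4 by a log2 change of −0.95 (adjusted p = 0.0301). Myh3, Tmprss11b and Akr1d1 lay under the lower quartile of the arrays on day 1, and Il6, Saa2 and Chil3 did so on at least 1 day 4 array, so their folds are approximate. Of the 10 rises Lrrc17, Tmprss11b and Cthrc1 kept their calls with any 1 array left out, and 3, 6, 4, 1, 3 and 3 of them lost theirs without day 1 wound replicates 1 and 2, day 4 wound replicates 1 and 2 and intact skin replicates 1 and 2 (highest adjusted p 0.139). Of the 10 falls Ly6g and Mmp8 kept theirs, and 5, 7, 8, 1, 8 and 8 were lost in that order (highest adjusted p 0.227).

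Lists of inflammatory, interferon and neutrophil genes were called down by camera from day 1 to day 4. Of 22 inflammatory cytokines and NF-kB targets 7 fell and none rose (17 adjusted over the list alone), with Nos2 at −1.55, the feedback inhibitor Socs3 at −1.37, the receptor antagonist Il1rn at −0.76 and Tnfaip3 at −0.69. The median was −0.53 (adjusted p = 2.04e-13, and adjusted p = 0.436 with an estimated correlation). Of 15 interferon-stimulated genes 1 fell, the protease Usp18 at −0.78 (13 adjusted over the list alone), while Ifit1 was at −0.68 (adjusted p = 0.0539). The median was −0.63 (adjusted p = 8.35e-12, and adjusted p = 0.436 with an estimated correlation). Of 14 neutrophil markers 5 fell and none rose (11 adjusted over the list alone). Their median was −0.70 (adjusted p = 2.23e-11, and adjusted p = 0.513 with an estimated correlation). Of 15 inflammatory chemokines 4 fell (8 and 2 higher adjusted over the list alone), Cxcl5 at −1.77, Ccl2 at −1.25, Cxcl1 at −1.07 and Ccl12 at −0.92. The median was −0.74 (adjusted p = 1.53e-05, and adjusted p = 0.436 with an estimated correlation). The monocyte and macrophage markers had a median of 0.08 and a mean of −0.09 (adjusted p = 0.557), and 2 rose and 2 fell (6 and 5 adjusted over the list alone), the complement genes C1qa and C1qc at 0.89 and 0.58 and Chil3 and Cd14 at −1.80 and −1.07. Dendritic and Langerhans cell markers had a median of 0.34 (adjusted p = 9.02e-04, and adjusted p = 0.513 with an estimated correlation), although limma called 0 of 13 (0 adjusted over the list alone and 7 at an unadjusted p under 0.05), with H2-Eb1 at 0.51 (adjusted p = 0.113). Limma called 0 of 10 mast cell markers (1 lower adjusted over the list alone, 2 at an unadjusted p under 0.05). Their median was −0.19 (adjusted p = 0.0448, and adjusted p = 0.516 with an estimated correlation). Cd4 was higher by 0.71 as the 1 T cell marker of 12 past the threshold (1 adjusted over the list alone), at a list median of 0.09 (adjusted p = 0.511). Limma called 0 of 9 B cell and plasma cell markers (2 higher adjusted over the list alone, 3 at an unadjusted p under 0.05), with Jchain at 1.08 (adjusted p = 0.0722). The list median was 0.07 (adjusted p = 0.13).

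The cell cycle, fibroblast and matrix lists were called up by camera between the days, with most of their members not passing on their own. Of 28 cell cycle genes 10 rose and none fell (21 adjusted over the list alone), the mitotic kinases Bub1 by 0.77, Cdk1 by 0.71 and Bub1b by 0.64 and the helicase Mcm6 by 0.55. The median was 0.40 (adjusted p = 1.05e-15, and adjusted p = 0.436 with an estimated correlation). The list's median relative to intact skin was 0.07 and 0.09 on the day 4 arrays. Of 14 fibroblast markers 3 rose and none fell (5 adjusted over the list alone), Col14a1 by 1.08, Dpp4 by 0.89 and Cd34 by 0.54. Their median was 0.36 (adjusted p = 1.97e-04, and adjusted p = 0.436 with an estimated correlation). Of 21 genes of the structural extracellular matrix 2 rose, the collagens Col5a2 by 0.57 and Col5a1 by 0.52, and Thbs1, an early matricellular protein, fell by 0.93 (10 and 2 adjusted over the list alone). The median was 0.35 (adjusted p = 3.68e-04, and adjusted p = 0.516 with an estimated correlation). Of 20 genes of differentiated epidermis 3 rose and none fell (5 adjusted over the list alone), Casp14 by 1.23, Tgm3 by 0.86 and Calm4 by 0.59. Their median was 0.15 (adjusted p = 0.0154, and adjusted p = 0.577 with an estimated correlation). Of 12 sebaceous gland genes 1 rose, Elovl3 by 0.75 (4 adjusted over the list alone). The median was 0.29 (adjusted p = 2.79e-04, and adjusted p = 0.513 with an estimated correlation). Of 12 smooth muscle, pericyte and myofibroblast markers 1 rose, Myl9 by 0.55 (3 adjusted over the list alone), and the actin Acta2 was at 0.30 (adjusted p = 0.112). The median was 0.16 (adjusted p = 0.029, and adjusted p = 0.513 with an estimated correlation). Of 14 circadian clock genes 1 rose, Bhlhe41 by 0.50 (4 adjusted over the list alone). Their median was 0.26 (adjusted p = 0.0159, and adjusted p = 0.513 with an estimated correlation). Cholesterol synthesis genes had a median of 0.12 (adjusted p = 0.00115, and adjusted p = 0.513 with an estimated correlation), and limma called 0 of 14 (3 higher adjusted over the list alone, 6 at an unadjusted p under 0.05), with Msmo1 at 0.36 (adjusted p = 0.0773). Melanocyte markers had a median of 0.40 (adjusted p = 0.0398, and adjusted p = 0.603 with an estimated correlation), and limma called 0 of 8 (0 adjusted over the list alone, 1 at an unadjusted p under 0.05), with Dct at 0.83 (adjusted p = 0.237).

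Skeletal muscle, hypoxia and growth factor lists were called down by camera between the days, with most of their members not passing on their own. Of 22 skeletal muscle markers 3 fell and none rose (12 adjusted over the list alone), the calcium buffer Pvalb by 1.21, Myh4 by 0.52 and Myoz1 by 0.51. The median was −0.38 (adjusted p = 1.85e-09, and adjusted p = 0.513 with an estimated correlation). Of 18 genes of hypoxia and glycolysis 1 fell, Ndrg1 by 0.62 (5 adjusted over the list alone). Their median was −0.17 (adjusted p = 2.19e-04, and adjusted p = 0.513 with an estimated correlation). The growth factors had a median of −0.25 (adjusted p = 0.0137, and adjusted p = 0.577 with an estimated correlation), and limma called 0 of 19 (1 higher and 3 lower adjusted over the list alone, 9 at an unadjusted p under 0.05), with Tgfb3 at 0.45 (adjusted p = 0.0631). The proteases and inhibitors had 3 falls and no rise (5 and 4 higher adjusted over the list alone), among them Adamts4 at −1.24 and Adamts1 at −0.61, at a median of −0.26 (adjusted p = 0.0862). Of 16 immediate early and heat shock genes 1 rose and 2 fell (2 and 6 adjusted over the list alone), the chaperone Hspa1a at 0.45, Fos at −0.59 and Egr1 at −0.48. The median was −0.08 (adjusted p = 0.13). The wound-edge keratinocyte genes had a median of 0.05 and a mean of −0.02 (adjusted p = 0.957), and 2 rose and 1 fell (4 and 4 adjusted over the list alone), Gjb6 at 0.48, Krt16 at 0.42 and the integrin Itgb6 at −0.66. Limma called 0 of 10 basal keratinocyte markers (0 adjusted over the list alone, 4 at an unadjusted p under 0.05), at a median of −0.13 (adjusted p = 0.0971). Limma called 0 of 16 endothelial markers (1 higher and 1 lower adjusted over the list alone, 4 at an unadjusted p under 0.05), with Flt1 at −0.45 (adjusted p = 0.0744). The list median was −0.15 (adjusted p = 0.118). Of 13 adipocyte markers 2 rose and none fell (3 and 2 lower adjusted over the list alone), Thrsp by 1.48 and the lipoprotein lipase Lpl by 0.55, at a median of 0.01 (adjusted p = 0.726) that was −0.03 with cyclic loess and −0.02 with median centring. Of the hair genes, Krt32 was at 0.62 (limma adjusted p = 0.305) and Krt28 at 1.88 (adjusted p = 0.521). The value of Krt28 is approximate, because it lay under the lower quartile on both wound arrays numbered 2 (4.85 and 5.03). The 21 hair genes had a median of 0.79 (camera adjusted p = 0.0981), and limma called 0 (0 adjusted over the list alone and 0 at an unadjusted p under 0.05). Their median difference turned to −0.58 without day 4 wound replicate 1 (adjusted p = 0.00334) and was 2.51 without day 1 wound replicate 1 (adjusted p = 4.64e-04), −0.15 without day 1 wound replicate 2 (adjusted p = 0.38) and 3.17 without day 4 wound replicate 2 (adjusted p = 1.28e-10). With a wound array left out, arrays of different numbers weigh more in the comparison, and between arrays of the same number the list's median went from −2.85 to −1.63 (number 1) and from −6.03 to −5.70 (number 2). Limma called 0 of 21 genes of oxidative phosphorylation (0 adjusted over the list alone, 4 at an unadjusted p under 0.05) and 0 of 6 Schwann cell markers (0 adjusted over the list alone, 2 at an unadjusted p under 0.05), at medians of 0.04 and 0.07 (adjusted p = 0.577 and 0.7).

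In all, 217 genes were higher and 227 lower on day 4 than on day 1, of which 30 and 76 differed at least 2-fold. The share of higher genes, 48.9%, was 39.2% with cyclic loess (191 and 296) and 39.3% with median centring (184 and 284). The counts were 24 and 50 without day 1 wound replicate 1, 4 and 11 without day 1 wound replicate 2, 9 and 5 without day 4 wound replicate 1, 67 and 117 without day 4 wound replicate 2, and 8 and 9 without either of the intact arrays, as with the 4 wound arrays alone. Camera called 10 lists up and 8 down, and 0 with an estimated correlation, where the lowest adjusted p was 0.436. Fry called 1, the cell cycle list (fry adjusted p = 0.0366). Calls that ended without day 1 wound replicate 1 were those for cholesterol synthesis (adjusted p = 0.0925), circadian clock (0.0536), melanocyte (0.0514), smooth muscle (0.131) and matrix genes (0.0528). Without day 1 wound replicate 2 the calls for differentiated epidermis (0.0935), growth factors (0.145), mast cells (0.244) and melanocytes (0.17) ended. Without day 4 wound replicate 1 those for growth factors (0.14), mast cells (0.244), melanocytes (0.14) and smooth muscle (0.119) ended, and without day 4 wound replicate 2 those for circadian clock (0.183), differentiated epidermis (0.179) and melanocytes (0.0716). Without the dimmest 50% of genes the calls for circadian clock (0.15), mast cells (0.373), melanocytes (0.167) and smooth muscle (0.0863) ended, and without the dimmest 30% those for circadian clock (0.0503), melanocytes (0.13) and smooth muscle (0.0614). Cyclic loess ended that for mast cells (0.0558). Of 48 list members that passed and were chosen by the rule, the 2 that kept their calls without any 1 array were Ly6g and Mmp8, and 39, 45, 46, 31, 45 and 45 were lost without day 1 wound replicates 1 and 2, day 4 wound replicates 1 and 2 and intact skin replicates 1 and 2.

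**Figure D2:**
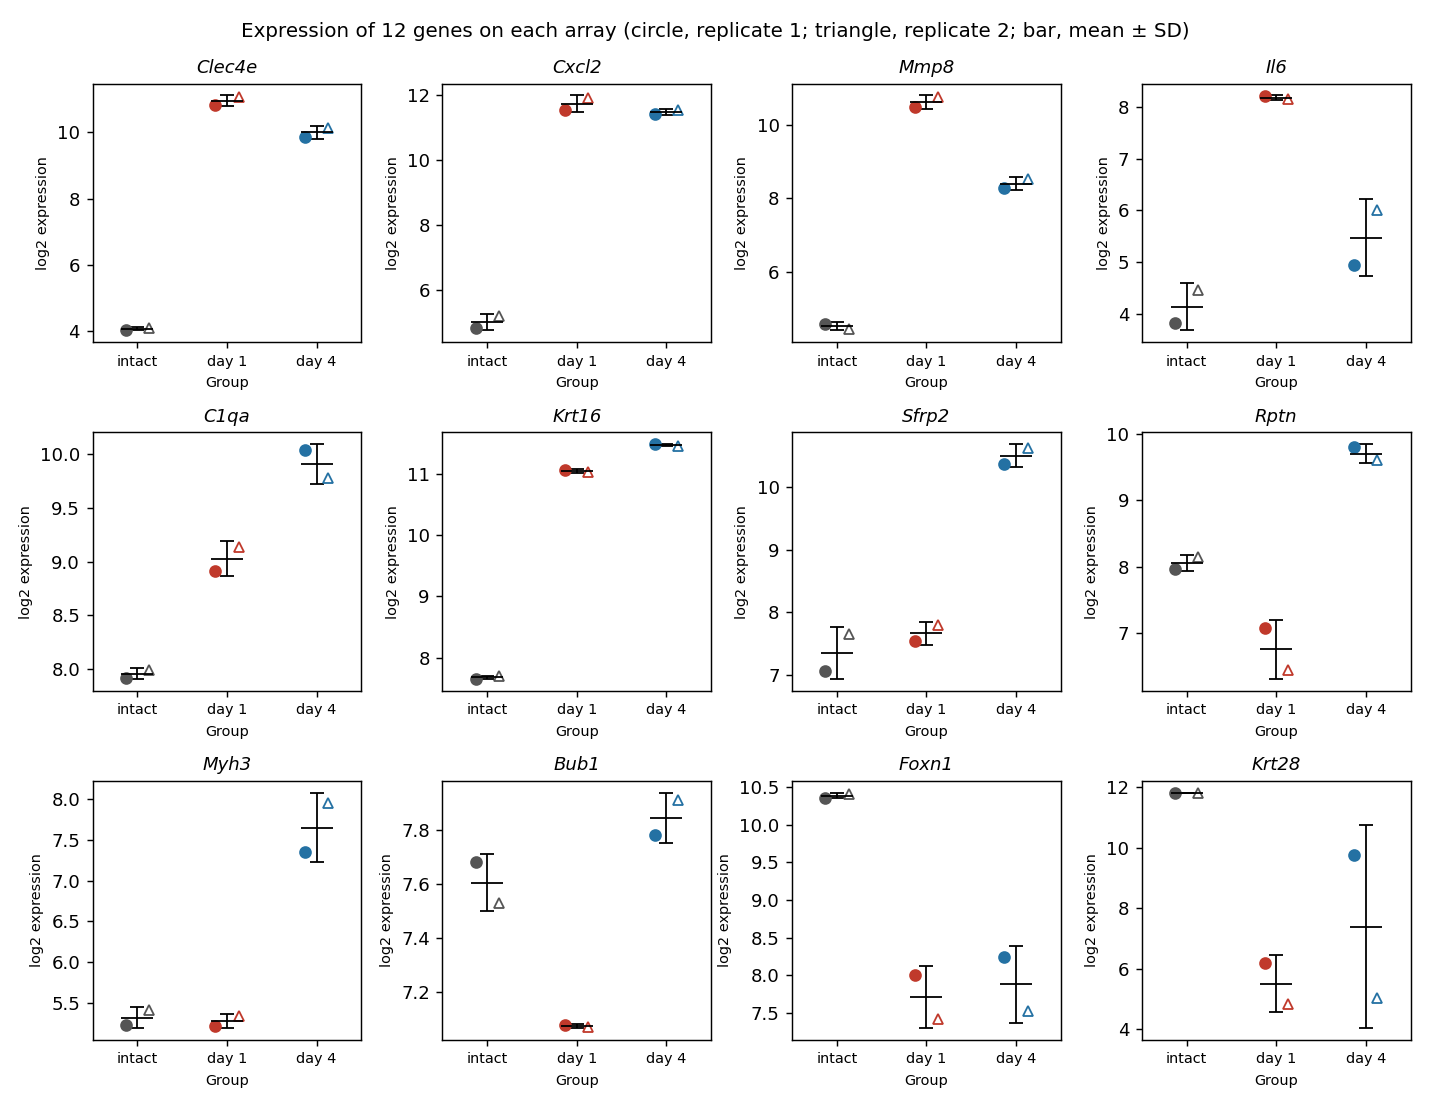
The log2 intensity (vertical axis) of 12 genes is plotted for intact skin, day 1 wounds and day 4 wounds (horizontal axis), with a point per array and bars for the group mean ± SD (n = 2). Clec4e, Cxcl2 and Mmp8 stand far above intact skin on both days, Rptn lies below intact skin on day 1 and above it on day 4, and Krt28 varies between replicates with an SD of 3.34 on day 4.

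Over both days, 2017 genes were higher than intact skin at both time points without a called difference between them, and 1822 were lower at both, where a missing call is not read as equality. An early peak, higher on day 1 and lower again on day 4 than on day 1, was called for 205 genes, among them Il6, Mmp8, Retnlg and Clec4e. A late rise was called for 121 genes, among them Sfrp2 and Cthrc1, an early trough for 100 genes and a late fall for 19. Without day 1 wound replicates 1 and 2, day 4 wound replicates 1 and 2 and intact skin replicates 1 and 2 in turn, the early peak held 50, 11, 5, 113, 9 and 9 genes and the late rise 19, 4, 9, 34, 7 and 7. In that order the early trough held 9, 1, 0, 36, 2 and 2 genes and the late fall 3, 0, 0, 8, 0 and 0. The genes higher at both days numbered 1097 and 1278 without intact skin replicates 1 and 2, and those lower at both numbered 1181 without day 1 wound replicate 2, 1012 without day 4 wound replicate 2, and 720 and 795 without intact skin replicates 1 and 2. Calls in the same direction on both days numbered 2178 higher and 1842 lower, where independent lists of that size would share 434.2 and 352.8. The fold changes of both days correlated across genes with r = 0.9279, and simulated unchanged groups that shared the 2 intact arrays gave a mean r of 0.5031 over 100 simulations, with 0 genes called by limma in common in either direction. The simulations drew the noise of each gene on its own and held no changed gene, so those 0 calls were nearly fixed beforehand. They do not measure how much of the overlap the shared intact arrays could create. The covariance was 0.3563 against 0.0193 in the simulations, and since both comparisons use the same 2 intact arrays, error in those arrays enters both.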

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

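All tests of explanations in this part were chosen after the result was seen.

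Day 4 wounds had 217 genes higher and 227 genes lower than day 1 wounds by limma's test, with a single intact group for both days. With 1 array left out these counts lay between 4 and 67 and between 5 and 117. For 11 of the genes the call against intact skin had opposite signs on the 2 days, and they were named after their values were seen. Of the 11, both opposite calls and the difference between the days stayed for 2 without day 1 wound replicate 1, for Rptn alone without day 1 wound replicate 2 or either intact array, and for 4 without day 4 wound replicate 2. Without day 4 wound replicate 1 this held for 0, as limma called the days different for none (11 at an unadjusted p under 0.05). Rptn was at −1.30 on day 1 and 1.65 on day 4 relative to intact skin (log2). Of the same kind were Itgbl1 (−0.32 and 0.63), Cercam (−0.36 and 0.39), Dpep1 (−0.51 and 0.42), Fscn1 (−0.35 and 0.34), Fxyd2 (−0.31 and 0.39) and the genes of dividing cells Aspm (−0.30 and 0.30), Hells (−0.38 and 0.25) and Parpbp (−0.32 and 0.26). Calcb (0.59 and −0.33) and Cnksr1 (0.50 and −0.43) had the opposite order.

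Of the 12146 probe sets outside the annotation, which the comparisons of genes do not use, 703 differed between day 1 wounds and intact skin, 377 higher and 326 lower, by up to 4.70 and down to −5.89 (log2). On day 4, 857 differed, 414 higher and 443 lower, by up to 4.06 and down to −4.49. Between the days limma called 0 of them, with 1752 at an unadjusted p under 0.05.

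Cell cycle genes had a median change of −0.33 on day 1 relative to intact skin and rose by a median of 0.40 from day 1 to day 4. Dilution by infiltrating cells, set as the cause of the day 1 value, would by itself lower basal keratinocyte markers alike. Their median was 0.34, and the means of the lists lay 0.52 apart with 2 standard errors over genes at 0.32. Genes of a list are not independent replicates. As 6 of the 10 basal markers rose on day 1, a rise after injury could hide a dilution, so dilution is not excluded. The return of the growing hair matrix, set as the cause of the rise, would raise matrix regulators at least as much. Their median change was 0.085, with the means 0.25 apart and 2 standard errors, again over genes, at 0.12. Loss of the growing hair matrix may account for the day 1 value. The cell cycle median was −0.32 on the higher of the 2 day 1 arrays, and the matrix regulators lay at −1.02 and −1.23. On day 4 the lists parted. The matrix regulators were still at a median of −1.01 relative to intact skin, and the cell cycle genes were at 0.07. A lower cell division in follicles on day 1 and a lower one in the epidermis cannot be told apart in whole skin. The time after injury itself stays open as an untested biological cause.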

How the results depend on the processing

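Of these alternatives, those leaving out both wound arrays with the same number were chosen after the data were seen. The F test and the time classes were counted again only with the mean-variance trend, without the dimmest 30% of genes, with the replicate block and with each array left out. Genes differing in the 3 comparisons were counted under every alternative. These counts stayed within 1.5 times the reported count except as follows. Between the days, the 4 wound arrays alone gave 8 higher and 9 lower (fewer arrays, so fewer degrees of freedom), and every probe set on its own gave 9 and 11. With the replicate block 348 genes were lower and 330 had an early peak. Between the days the block also gained calls for 12 results of named genes and 3 lists. Same-numbered arrays of day 1 and day 4 deviated from their group means alike (r = 0.6853 across genes, 0.4710 without 102 keratin and hair genes), and with intact skin r was 0.0139 and 0.0227. The reported fit did not pair samples by number, because the labels do not say what the numbers mark. A factor shared by same-numbered wound arrays is not excluded. A mean-variance trend gave 30 late falls. With the wound arrays numbered 1 left out the counts were 1391 and 1118 on day 1, 793 and 688 on day 4 and 0 and 0 between the days (limma, 2987 at an unadjusted p under 0.05). With those numbered 2 left out they were 615 and 498, then 0 and 0 (6314) and 0 and 0 (2822). Fewer arrays entered those fits. For the results of named genes, leaving out those numbered 1 ended 32 calls and left 110 results as they were on day 1, 55 and 92 on day 4, and 64 and 71 between the days. Leaving out those numbered 2 gave 70 and 72, 139 and 8, and 64 and 71. The 4 wound arrays alone ended 55 calls between the days and left 80 results as they were, and a robust prior ended 11, 8 and 3 in the 3 comparisons. Every other alternative with all 6 arrays ended at most 6 in a comparison among the genes it still tested. For every probe set alone, the block, the robust prior and the trend the cause was not tested. With each array left out in turn, the F test gave 2396 to 5229 genes, day 1 gave 1773 to 2901 higher and 1376 to 2772 lower, day 4 gave 1393 to 2760 and 853 to 2147, and the days differed in 4 to 67 and 5 to 117. The early peak ranged from 5 to 113, the late rise from 4 to 34, the early trough from 0 to 36, the late fall from 0 to 8, genes higher at both days from 1097 to 2041 and lower at both from 720 to 1459. Leaving out an intact array gave the wound comparison the residual degrees of freedom of the 4 wound arrays alone. The hair list's change between the days, 0.79, reversed to −0.58 without day 4 wound replicate 1 and reached 3.17. Of 21 lists called on day 1, 16 kept their calls in all alternatives with the preset correlation, as did 16 of 23 on day 4 and 10 of 18 between the days, and 0 were called with an estimated correlation. A robust prior was not run for list tests, because camera has no such option. No normalization moved the median of all genes by more than 0.1.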

Other observations

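Of the tests in this part only that of a second list of regenerating muscle genes was chosen before its result was seen. The lists of matrix regulators, bulge markers, embryonic and regenerating muscle genes and the genes of stressed muscle were chosen after seeing the data, while the hair, basal keratinocyte, sebaceous, adipocyte and adult muscle lists were chosen before.

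Regulators of the growing hair matrix were lower in wounds on both days: all 11 measured fell on day 1 and all 11 on day 4, and at least 8 did so with any 1 array left out. The Wnt effector Lef1 was at −2.50 and −2.41, Fgf5, which ends the growth phase, at −2.76 and −2.26, the homeobox gene Dlx3 at −2.63 and −2.48 and the signal Shh at −0.94 and −0.90. Markers of the follicle's bulge, where its stem cells lie, went both ways, with 3 lower and 1 higher (Nfatc1) of 7 on day 1 and 4 lower and 2 higher (Nfatc1 and Cd34) on day 4. Cd34 also stood in the fibroblast list, so in whole skin these markers do not stand for the bulge alone. The counts changed when any array of a compared group was left out, which leaves 1 array in that group and fewer degrees of freedom, so single calls are uncertain. The list's median on day 1 was −0.75, and −0.84, −0.545, −0.93 and −0.57 without day 1 wound replicates 1 and 2 and intact skin replicates 1 and 2. On day 4 it was −0.675, and −0.69, −0.66, −0.855 and −0.495 without day 4 wound replicates 1 and 2 and intact skin replicates 1 and 2.

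Of 10 embryonic muscle genes 7 rose from day 1 to day 4, and all 10 were higher on day 4 than in intact skin, against 2 on day 1. The 7 fell to 1 without day 1 wound replicate 1 or either intact array, to 4 without day 4 wound replicate 1 and to 0 without day 1 wound replicate 2 (limma, 9 at an unadjusted p under 0.05). The 10 fell to 6 without intact skin replicate 2, and the 2 to 1 without either day 1 array or either intact array. From day 1 to day 4 the embryonic myosin Myh3 rose by 2.37, Actc1 by 2.25, Myl4 by 1.27, Tnni1 by 1.27, the fusion factor Mymk by 1.23 and Tnnc1 by 1.15. Of 4 genes known from stressed muscle, which form no tested list, Ankrd1 was at 4.46 on day 1 and 2.09 on day 4 relative to intact skin, Rrad at 3.69 and 1.09, Xirp1 at 1.73 and −0.11 and Csrp3 at 1.47 and −0.05. The change between the days passed for Ankrd1, Rrad and Xirp1, and for Csrp3 it was −1.52 (adjusted p = 0.0841). All 3 lost that call without day 1 wound replicate 2 or day 4 wound replicate 1, Ankrd1 and Rrad also without either intact array, and Ankrd1 without day 1 wound replicate 1. The day 1 call of Csrp3 was lost without day 1 wound replicate 1 or intact skin replicate 1, the day 4 call of Ankrd1 without intact skin replicate 1, and that of Rrad without day 4 wound replicate 2 or either intact array. Of 14 further genes of regenerating muscle, 4 were higher and 2 lower on day 1 and 3 higher on day 4 than in intact skin. On day 1 this became 4 and 1 without day 1 wound replicate 1, 1 and 0 without day 1 wound replicate 2 or intact skin replicate 1, and 3 and 0 without intact skin replicate 2. The 3 became 7 without day 4 wound replicate 1 and 0 without intact skin replicates 1 and 2 (limma, 3 and 5 at an unadjusted p under 0.05).

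The hair shaft and root sheath genes were lower in wounds, by more than the wound's share of the biopsy area alone would give. On the wound array with the smallest fall of the 4 their median was −1.63. All 21 lay below the bound of −0.42 that the wound's area sets (standard error of the list mean 0.10). That bound takes the wound's size when punched and equal RNA per area, and it ignores dilution by infiltrating cells. On the same array the medians of basal keratinocyte, sebaceous gland and adipocyte markers were 0.14, 0.27 and −0.16, all above the bound. A rise of such markers after injury could hide a dilution, so a share of dilution in the fall is not excluded. Follicles out of the growth phase may account for the fall. The highest of the 4 wound arrays' medians of matrix regulators was −0.90, and all 4 lay below the 2.5th percentile of matched random lists. So did those of the bulge markers (−0.55, −0.84, −0.66 and −0.69), which do not stand for the bulge alone in whole skin. The matrix list was chosen after the data were seen, and the random genes were drawn independently of each other. A low percentile is therefore no support by itself. For these reasons the test cannot decide, which keeps that explanation open. Animals in different hair cycle phases whatever the wound, or pools of them, cannot be told apart from an effect of wounding with 2 arrays a group, because replicates differed by 3.18 on day 1 and 4.07 on day 4 beside mean falls of 4.44 and 3.67.

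The rise of embryonic muscle genes was set against more muscle in the day 4 biopsies, which would raise adult fibre markers too, but their median changed by −0.38 from day 1 to day 4 while that of the embryonic genes was 1.19. Regenerating muscle is a candidate explanation: a second list of 14 such genes had a median change of 0.22, above the upper end (0.12) of the central range of matched random lists. Limma called 0 of these 14 between the days (7 at an unadjusted p under 0.05). Between the days its members went both ways, with Ncam1 at 0.81 and Chrnb1 at −0.66, neither of which passed, so the support is weak. As the pattern was found in these data, this is a hypothesis, and which muscle layer the biopsies held was not tested.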
